A study of Mus musculus with 12 samples.

How the data were processed

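Spinal cord of mice at postnatal day 21 was sampled from 2 bacTRAP lines, which express EGFP-tagged Rpl10a from Chat or Snap25 sequences. Per the labels, ribosomes were pulled down for 4 h at 4 degrees C, RNA was extracted with TRIzol, treated with DNase and purified, and cDNA was amplified with the Nugen Ovation RNA-Seq V2 kit before sequencing on a HiSeq2500. The groups PreIP_Snap25, PreIP_Chat, TRAP_Snap25 and TRAP_Chat, of 3 libraries each, were taken from the sample titles. The descriptions of an input and of the pulldown with the same replicate number share a suffix, whose meaning is not stated.

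The deposited table holds raw read counts per Ensembl gene for each library, made by the authors with STAR and HTSeq per the submitters' processing notes. Versions, genome build, annotation release and strand setting are not given in the sources used here. Its values are whole numbers. It has 41736 lines for 40912 gene IDs, since 824 lines repeat another line exactly (485 IDs), and each repeat was dropped. Another 86 gene names are shared by several IDs, which were kept apart. Reads over overlapping genes cannot be assigned with certainty while the strand setting is unknown. No coordinates are printed for the same reason, and GENCODE M21, which placed 15849 of the 15905 tested genes (99.6%), was used only for which genes lie next to each other.

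Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with the groups and default settings, libraries were scaled by TMM, and all 12 libraries were fitted together with 1 mean per group (glmQLFit, glmQLFTest). The 5 comparisons were each pulldown with its input, the pulldowns of the lines, the difference between the lines in the change from input to pulldown, and the inputs of the lines. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 15905 tested genes, with a threshold of 0.05. Log2 fold changes are given with the standard error from the quasi-likelihood fit. CPM are the scaled counts that the edgeR function cpm gives, after TMM, except that the floor of 3 counts, immunoglobulin levels and levels relative to the input are shares of total counts with no such scaling. Genes for which the libraries of both groups did not overlap were counted, which by chance holds for 10% of genes.

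A total of 27 gene lists of at least 4 tested genes were written by hand from general knowledge. They cover cholinergic motor neurons, motor neuron subtypes, other cholinergic neurons, GABAergic and glycinergic neurons, glutamatergic neurons, neurons in general, the axonal cytoskeleton, voltage-gated channels, transmitter receptors, ALS-linked genes, Hox genes, immediate early genes, oligodendrocytes and their precursors, astrocytes, microglia, vessels, fibroblasts, ependymal cells, Schwann cells and sensory neurons, muscle, blood, the cytosolic ribosome, nuclear and mitochondrial genes of respiration, nuclear RNA and sex-linked genes. Of 435 genes tested in the lists, 14 stand in several lists and Prph stands in 3. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and again with the correlation estimated. The latter kept 4 calls, those of the cholinergic motor neuron list and of the inhibitory list in TRAP_Chat against TRAP_Snap25 and in the difference between the lines. The set test fry, which does not compare a list with other genes, was run beside them.

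The comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. Genes named are Chat, Snap25 and Rpl10a, the 5 largest rises and 5 largest falls of each comparison (3 each for the inputs) among genes past the threshold with a mean of at least 5 CPM over the groups compared and no overlap of replicates, and up to 2 members per list and direction. Predicted genes and ribosomal pseudogenes were left out of these, some list members were left out of the text, and 1 gene that the rule names is not reported here. The values of Clic1 and S100a11 in the separate pulldowns, the muscle genes by library, Ercc6 and the other neighbours of Chat and Snap25, and the immunoglobulin genes fall outside this rule and were chosen after their values were seen. The pipeline was tested on simulated data in which 200 genes with a mean of at least 1 CPM were changed. At a true 4-fold change it recovered 74.7%, 73.0%, 69.7%, 40.4% and 71.0% of them in the 5 comparisons, in the order given, and at 2-fold 6.0%, 19.0%, 6.0%, 0% and 8.0%. Of the calls 4.76%, 7.07%, 3.85%, 4.76% and 4.82% were false. The simulation gave all groups the same spread for each gene, whereas in the data the pulldowns varied more than the inputs. These shares therefore do not give the error rate or recovery for the real pulldowns or inputs.

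The alternatives were RLE scaling, DESeq2 1.42.0, limma voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block (for pulldown against input and the difference between the lines, each input with the pulldown of its line, number and suffix), and each library left out in turn. Where a library was left out, its group kept 2 libraries. A fit of protein-coding genes only was added after the data had been seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. All 12 libraries were used. Replicates of each group differed by more than counting noise, with chi-square per degree of freedom from 18.9 to 192 between pairs, so none was counted as a repeat of another.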

Results

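The data were RNA sequencing counts from 12 libraries of mouse spinal cord at postnatal day 21. The mice carried 1 of 2 bacTRAP transgenes, which express the ribosomal protein Rpl10a fused to EGFP from sequences of Chat, a gene of cholinergic neurons, or of Snap25, a gene of neurons in general. The tag lets ribosomes of the cells that express it be pulled down together with the RNA they hold. Each line gave 3 libraries of pulled-down RNA (TRAP) and 3 of RNA taken before the pulldown (PreIP, the input). Total counts ran from 10149346 to 20521699 per library, with group means of 19.3 ± 1.33 M in PreIP_Chat, 18.7 ± 1.44 M in PreIP_Snap25, 14.8 ± 1.60 M in TRAP_Chat and 11.9 ± 2.26 M in TRAP_Snap25 (SD, n = 3). Of 40912 gene IDs, 14335 had no count in any library and 15905 passed the filter on low counts and were tested. A count of 3 corresponded to between 0.146 and 0.296 CPM in a single library, over total counts without TMM scaling. Such limits cover counting error only.

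RNA of the mitochondrial ribosome made up 25.0% ± 1.59 of the counts in PreIP_Chat, 33.0% ± 7.71 in PreIP_Snap25, 2.44% ± 3.66 in TRAP_Chat and 0.441% ± 0.236 in TRAP_Snap25 (SD, n = 3). Across all tested genes the first principal component of log2 CPM held 44.1% of the variance and separated the TRAP from the PreIP libraries, and the second held 14.7% and separated the TRAP libraries of the lines. Replicates of the pulldown varied more than those of the input, with a biological coefficient of variation of 0.479 in TRAP_Chat and 0.495 in TRAP_Snap25 against 0.231 in PreIP_Chat and 0.285 in PreIP_Snap25. The labels do not say whether the replicates came from separate animals, so p-values measure only the spread between these samples.

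The Chat pulldown was first compared with its own input, to see which RNAs were held more or less by ribosomes of the tagged cells. Genes of cholinergic motor neurons rose together. All 20 measured members of that list were higher in TRAP_Chat, with a median 9.03-fold rise, and 20 passed when adjusted over the list alone. Chat, which makes acetylcholine, rose 7.18-fold (log2 fold change 2.84 ± 0.30, SE, n = 3 per group, edgeR adjusted p = 1.61e-05), from 22.2 ± 7.24 to 159 ± 46.4 CPM (SD). Calcb, which encodes a calcitonin gene-related peptide, rose by 3.90 ± 0.41 on the log2 scale (SE). The list passed camera (adjusted p = 2.4e-19), but not once the correlation between genes was estimated from these libraries (adjusted p = 0.0512 with an estimated correlation).

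**Figure D1:**
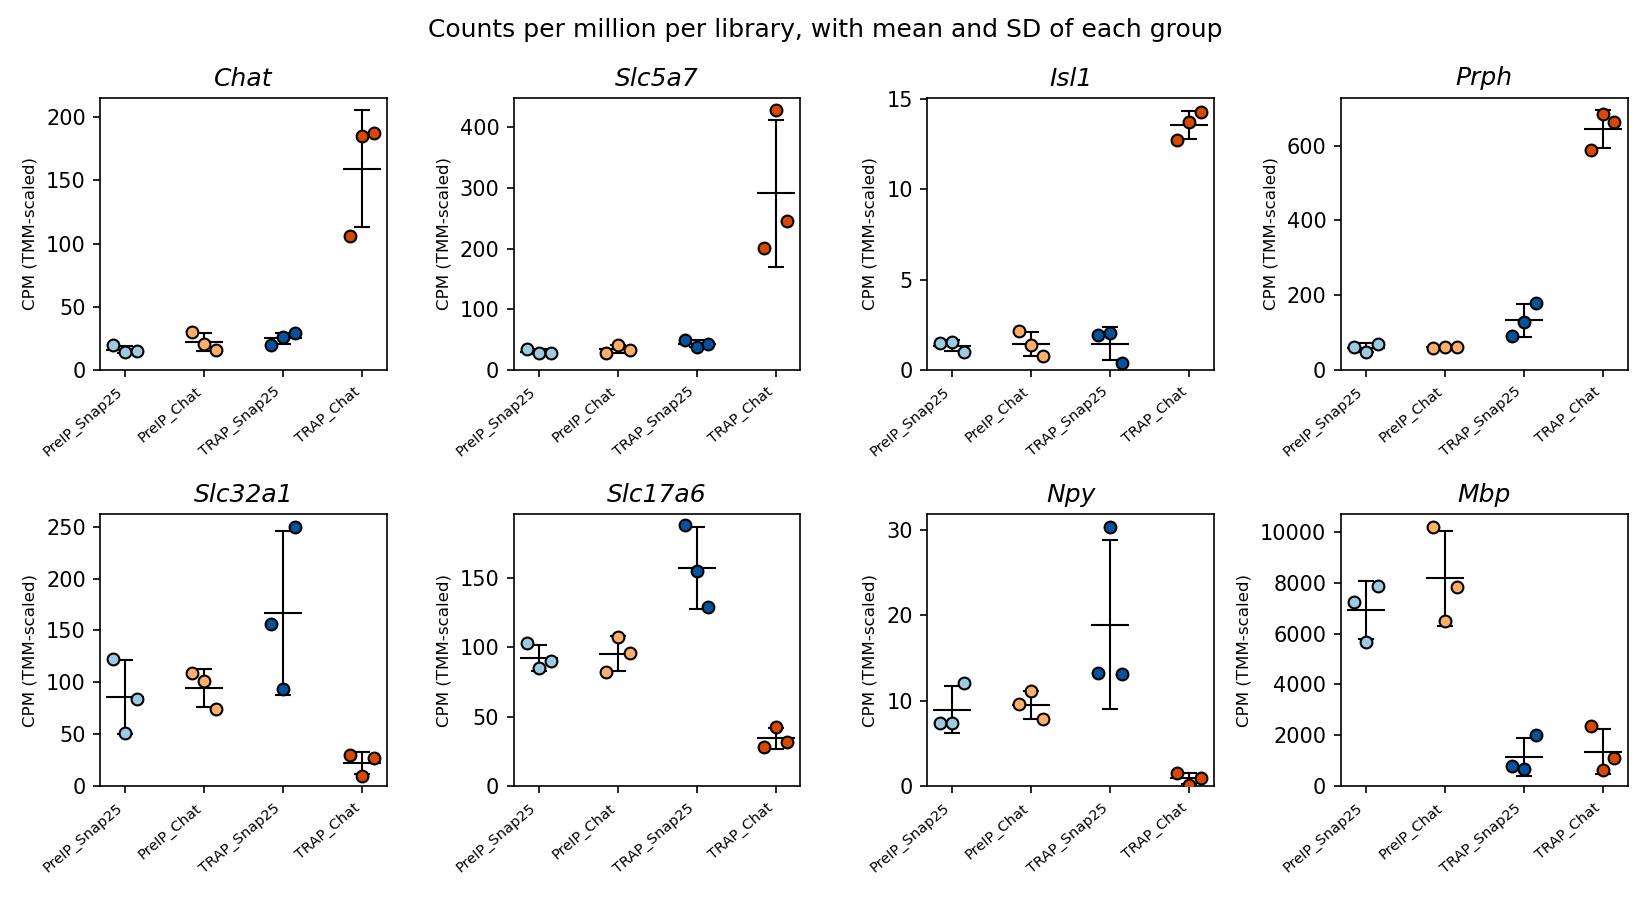
CPM, scaled by TMM, of 8 genes (vertical axes, linear from 0) in each of the 12 libraries (points), with the mean and SD of each group of 3 as bars. Chat, Slc5a7, Isl1 and Prph were highest in the 3 TRAP_Chat libraries, Slc32a1, Slc17a6 and Npy were lowest there, and Mbp was lower in the TRAP libraries of both lines than in their inputs.

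The genes with the largest rises in TRAP_Chat over PreIP_Chat included several that encode secreted peptides. Uts2, which encodes urotensin 2, rose 26.0-fold (log2 fold change 4.70 ± 0.44, SE, edgeR adjusted p = 5.84e-06), Uts2b, which encodes a related peptide, 15.1-fold, and Cartpt, which encodes a neuropeptide precursor, 15.6-fold. Amhr2, a receptor of anti-Müllerian hormone, rose 18.2-fold and Rasl10a, a small GTPase, 15.0-fold. Among 11 markers of motor neuron subtypes 5 rose and 2 fell, or 8 and 2 adjusted over the list alone. Chodl, a marker of fast motor neurons, rose 11.8-fold, Spp1, which encodes osteopontin, rose 6.13-fold, and Sv2a, a synaptic vesicle protein, fell 3.01-fold. Of 17 genes of the axonal cytoskeleton 6 rose and 1 fell (8 and 2 adjusted over the list alone). Prph, which encodes peripherin, rose 10.6-fold and Stmn2, a microtubule regulator of growing axons, 4.07-fold. Both lists passed camera (adjusted p = 0.00474 and 0.00707), and both had adjusted p = 0.261 with an estimated correlation.

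Markers of inhibitory neurons fell in the Chat pulldown. Of 17 measured genes of GABAergic and glycinergic neurons 14 fell and 3 did not pass (14 lower and 1 higher adjusted over the list alone). Npy, which encodes neuropeptide Y, fell 10.3-fold (log2 fold change -3.37 ± 0.56, SE, edgeR adjusted p = 0.000539), and Sall3, a transcription factor, fell 8.15-fold. The list had a median log2 fold change of -1.65 and passed camera (adjusted p = 6.35e-06, and adjusted p = 0.0512 with an estimated correlation). Markers of glutamatergic neurons went both ways, 7 of 17 lower and 3 higher (8 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.183). Among them Slc17a7, a vesicular glutamate transporter, fell 5.66-fold, whereas the peptide genes Nts and Sst rose 4.34-fold and 2.25-fold. Genes of neurons in general had a median log2 fold change of 0.16, with 3 of 25 higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.495). The RNA-binding proteins Elavl3 and Celf4 fell 3.16-fold and 2.84-fold, and Snap25 itself had a log2 fold change of 0.38 ± 0.26 (SE, edgeR adjusted p = 0.297).

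Markers of glia fell in the Chat pulldown. All 18 markers of oligodendrocytes fell, among them Opalin, which encodes a myelin-associated protein, 8.43-fold, and Mag, which encodes myelin-associated glycoprotein, 7.07-fold. All 12 markers of oligodendrocyte precursors fell (Enpp6 7.15-fold), as did 16 of 19 markers of astrocytes, with 2 higher (Gfap 6.52-fold and Apoe 7.60-fold lower), and 10 of 16 markers of microglia (C1qa from 3.97 ± 1.43 to 0.202 ± 0.231 CPM, SD). Adjusted over the list alone, 18, 12, 17 and 13 members of these lists fell. Median log2 fold changes were -2.33, -2.46, -2.03 and -2.38, each list passed camera (adjusted p = 3.99e-09, 1.11e-07, 2.35e-06 and 1.54e-06), and each had adjusted p = 0.261 with an estimated correlation. TRAP_Chat replicate 1 held these glial RNAs at other levels than its fellow replicates. Its oligodendrocyte list stood at 37.7% of the mean of PreIP_Chat, against 11.5% and 23.4% in replicates 2 and 3. For astrocytes the levels were 42.2%, 14.1% and 29.4%, for oligodendrocyte precursors 35.9%, 9.85% and 16.7%, and for microglia 18.9%, 15.6% and 20.4%.

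RNAs that cytosolic ribosomes do not translate fell as well. Of 8 measured protein genes of the mitochondrial genome 6 fell (8 adjusted over the list alone), with a median log2 fold change of -3.06. The subunit gene mt-Nd6 fell 30.6-fold, mt-Rnr2, an RNA of the mitochondrial ribosome, 14.4-fold, and Rmrp, a noncoding RNA of an RNA-processing enzyme, 28.6-fold. Of 10 long noncoding RNAs kept in the nucleus 7 fell (7 lower and 1 higher adjusted over the list alone), among them Malat1 10.6-fold and Miat 12.5-fold. Camera gave adjusted p = 0.000156 for the mitochondrial list (adjusted p = 0.266 with an estimated correlation) and 0.0163 for the nuclear list (adjusted p = 0.261 with an estimated correlation). Without TRAP_Chat replicate 3 the nuclear list had a camera adjusted p of 0.0509. In TRAP_Chat replicate 1 the 2 RNAs of the mitochondrial ribosome stood at 26.7% of the mean of PreIP_Chat, against 1.21% and 1.43% in replicates 2 and 3, and the mitochondrial messenger RNAs at 38.6%, against 3.20% and 3.33%. Without that library log2 fold changes were -6.81 for mt-Nd6, -6.87 for mt-Rnr2, -6.08 for Rmrp and -4.60 for Malat1, and at the other end -4.46, -3.28 and -2.89 for mt-Nd6, mt-Rnr2 and Malat1 without replicate 2 and -4.34 for Rmrp without replicate 3.

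Nuclear genes of the respiratory chain rose: 13 of 26 passed (15 adjusted over the list alone), among them Ndufb5 3.54-fold and Cox6c 3.35-fold, both subunits of its complexes (camera adjusted p = 2.77e-06, and adjusted p = 0.266 with an estimated correlation). Of 33 genes of the cytosolic ribosome 5 rose, and 0 passed adjusted over the list alone with edgeR, where 12 rose at an unadjusted p under 0.05. DESeq2 and limma voom gave 7 and 0 of them adjusted over the list alone. That list passed camera (adjusted p = 0.00536, and adjusted p = 0.534 with an estimated correlation). All 5 genes of red blood cells fell (camera adjusted p = 0.00196), as did 6 of 11 markers of meningeal fibroblasts (10 adjusted over the list alone, 0.000841) and 6 of 16 markers of blood vessels, with 1 higher (6 and 1 adjusted over the list alone, 0.00379). These 3 lists had adjusted p = 0.261 with an estimated correlation. Hbb-bt, a beta globin, fell 7.38-fold, Slc6a13, a GABA transporter of the meninges, 11.9-fold, and Vtn, which encodes vitronectin, 7.91-fold, whereas Itm2a, a membrane protein, rose 3.97-fold.

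In all, 2005 genes were higher and 2268 lower in TRAP_Chat than in PreIP_Chat (edgeR, adjusted p under 0.05), of which 1412 and 2014 changed over 2-fold, and 6205 had an unadjusted p under 0.05. The 3 libraries of each group did not overlap for 7614 genes, or 47.9% of those tested, where chance gives 10%. Without PreIP_Chat replicate 1, 2 or 3 the count of higher genes was 1314, 1191 or 1315.

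The Snap25 pulldown was compared with its own input in the same way. Nuclear genes of the respiratory chain rose most widely, 19 of 26 over all genes and 24 adjusted over the list alone, and all 26 log2 fold changes were positive. Ndufb5 rose 3.64-fold (log2 fold change 1.86 ± 0.29, SE, n = 3 per group, edgeR adjusted p = 0.000478) and Cox5a 2.96-fold. Uqcrb and Ndufa6, further subunits of the chain, were among the 5 largest rises of all tested genes at 4.08-fold and 4.07-fold, with Uts2 at 4.72-fold, Popdc3 at 4.65-fold and Rpp25, a subunit of an RNA-processing enzyme, at 4.15-fold. The list passed camera (adjusted p = 3.53e-11, and adjusted p = 0.189 with an estimated correlation).

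Of 20 cholinergic motor neuron genes 12 rose (13 adjusted over the list alone), with a median log2 fold change of 1.19 (camera adjusted p = 5.87e-06, and adjusted p = 0.189 with an estimated correlation). Prph rose 2.22-fold, and Chat had a log2 fold change of 0.63 ± 0.29 (SE, edgeR adjusted p = 0.131). Of 25 genes of neurons in general 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a median log2 fold change of 0.59. Vsnl1, a neuronal calcium sensor, rose 3.01-fold and Elavl3 fell 3.80-fold. Snap25, the gene that gives the line its name, had a log2 fold change of 0.73 ± 0.26 (SE, edgeR adjusted p = 0.0544). That list passed camera (adjusted p = 0.0134, and adjusted p = 0.305 with an estimated correlation), but not without TRAP_Snap25 replicate 3 (adjusted p = 0.0610). Of 33 transmitter receptors 7 rose and 2 fell (8 and 2 adjusted over the list alone), among them Glrb, a glycine receptor subunit, 2.41-fold higher (camera adjusted p = 0.0116, adjusted p = 0.343 with an estimated correlation, and 0.0556 by camera without TRAP_Snap25 replicate 1). Of 25 Hox genes, which are expressed by position along the cord, 4 rose (2 adjusted over the list alone), among them Hoxc10 2.27-fold and Hoxb5 2.10-fold (camera adjusted p = 0.00628, and adjusted p = 0.189 with an estimated correlation).

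Glial and other markers fell in the Snap25 pulldown too. All 18 oligodendrocyte markers fell (Ermn 9.55-fold), as did 11 of 12 precursor markers (Neu4 10.3-fold), 16 of 19 astrocyte markers (Sox9 13.3-fold, Slc1a3 10.4-fold) and 12 of 16 microglial markers (Trem2 to 0.136 ± 0.235 CPM, SD). Adjusted over the list alone the counts were 18, 12, 17 and 15. Camera gave adjusted p = 9.95e-12, 7.12e-09, 1.25e-08 and 2.63e-09, and each list had adjusted p = 0.189 with an estimated correlation. TRAP_Snap25 replicate 3 held the oligodendrocyte list at 29.4% of the mean of PreIP_Snap25, against 15.8% and 11.6% in replicates 1 and 2, and the microglial list at 23.0%, against 14.7% and 5.04%. Its mitochondrial messenger RNAs stood at 10.3%, against 4.87% in replicate 1 and under 2% in replicate 2, and RNA of the mitochondrial ribosome at 1.32%, against 2.06% and 0.632%.

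All 8 mitochondrial protein genes fell in the Snap25 pulldown (median log2 fold change -4.43, 8 adjusted over the list alone, camera adjusted p = 5.87e-06, and adjusted p = 0.231 with an estimated correlation), and mt-Rnr2 fell 111-fold and mt-Rnr1 74.7-fold. Of the nuclear noncoding RNAs 6 of 10 fell (7 adjusted over the list alone, camera adjusted p = 0.00477, and adjusted p = 0.212 with an estimated correlation), among them Malat1 20.8-fold (log2 fold changes from -5.95 without TRAP_Snap25 replicate 3 to -3.90 without replicate 2), and Mir124a-1hg, the host of a neuronal microRNA, fell 33.9-fold. The nuclear list stood at 63.2% of the input in TRAP_Snap25 replicate 1, against 32% and 27.1% in replicates 2 and 3, and the red blood cell genes at 23.0%, against 16.5% and 13.8%. All 5 red blood cell genes fell (5 adjusted over the list alone, Hbb-bs 8.17-fold, camera adjusted p = 4.04e-05), as did 6 of 11 fibroblast markers (8 adjusted over the list alone, Ptgds 9.59-fold, 0.000144) and 1 of 7 ependymal markers (3 adjusted over the list alone, Ccdc153 from 4.36 ± 0.264 to 0.156 ± 0.190 CPM, SD, 0.00199). These 3 lists had adjusted p = 0.189 with an estimated correlation. Vascular markers fell in 4 of 16 cases (4 adjusted over the list alone, Cdh5 8.68-fold, camera adjusted p = 0.00477, and adjusted p = 0.290 with an estimated correlation).

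In this line 1541 genes were higher and 2017 lower in the pulldown (edgeR), of which 853 and 1844 changed over 2-fold, and 5609 had an unadjusted p under 0.05. The libraries of both groups did not overlap for 6043 genes, or 38.0%, where chance gives 10%. The count of higher genes was 739 without PreIP_Snap25 replicate 1, 675 without PreIP_Snap25 replicate 2, 950 without TRAP_Snap25 replicate 2 and 890 in a fit of these 6 libraries alone, and that of lower genes was 1298 without PreIP_Snap25 replicate 2.

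Both pulldowns shared many genes. Of the genes higher in each, 921 were the same, where 194 would be shared by chance (odds ratio 18.2), and of those lower in each 1222 were the same, where 288 would be (odds ratio 18.9). The one-sided Fisher exact test, which takes genes as independent, put the 95% lower limits of these odds ratios at 16.4 and 17.2. Another 12 genes were higher in the Chat pulldown and lower in the Snap25 pulldown, and 16 the reverse. Across genes, which are not independent replicates, log2 fold changes of the lines had a Pearson correlation of 0.608 and a Spearman correlation of 0.646. The number of shared higher genes was 496 without PreIP_Snap25 replicate 1, 493 without PreIP_Snap25 replicate 2 and 584 without PreIP_Chat replicate 2.

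**Figure D2:**
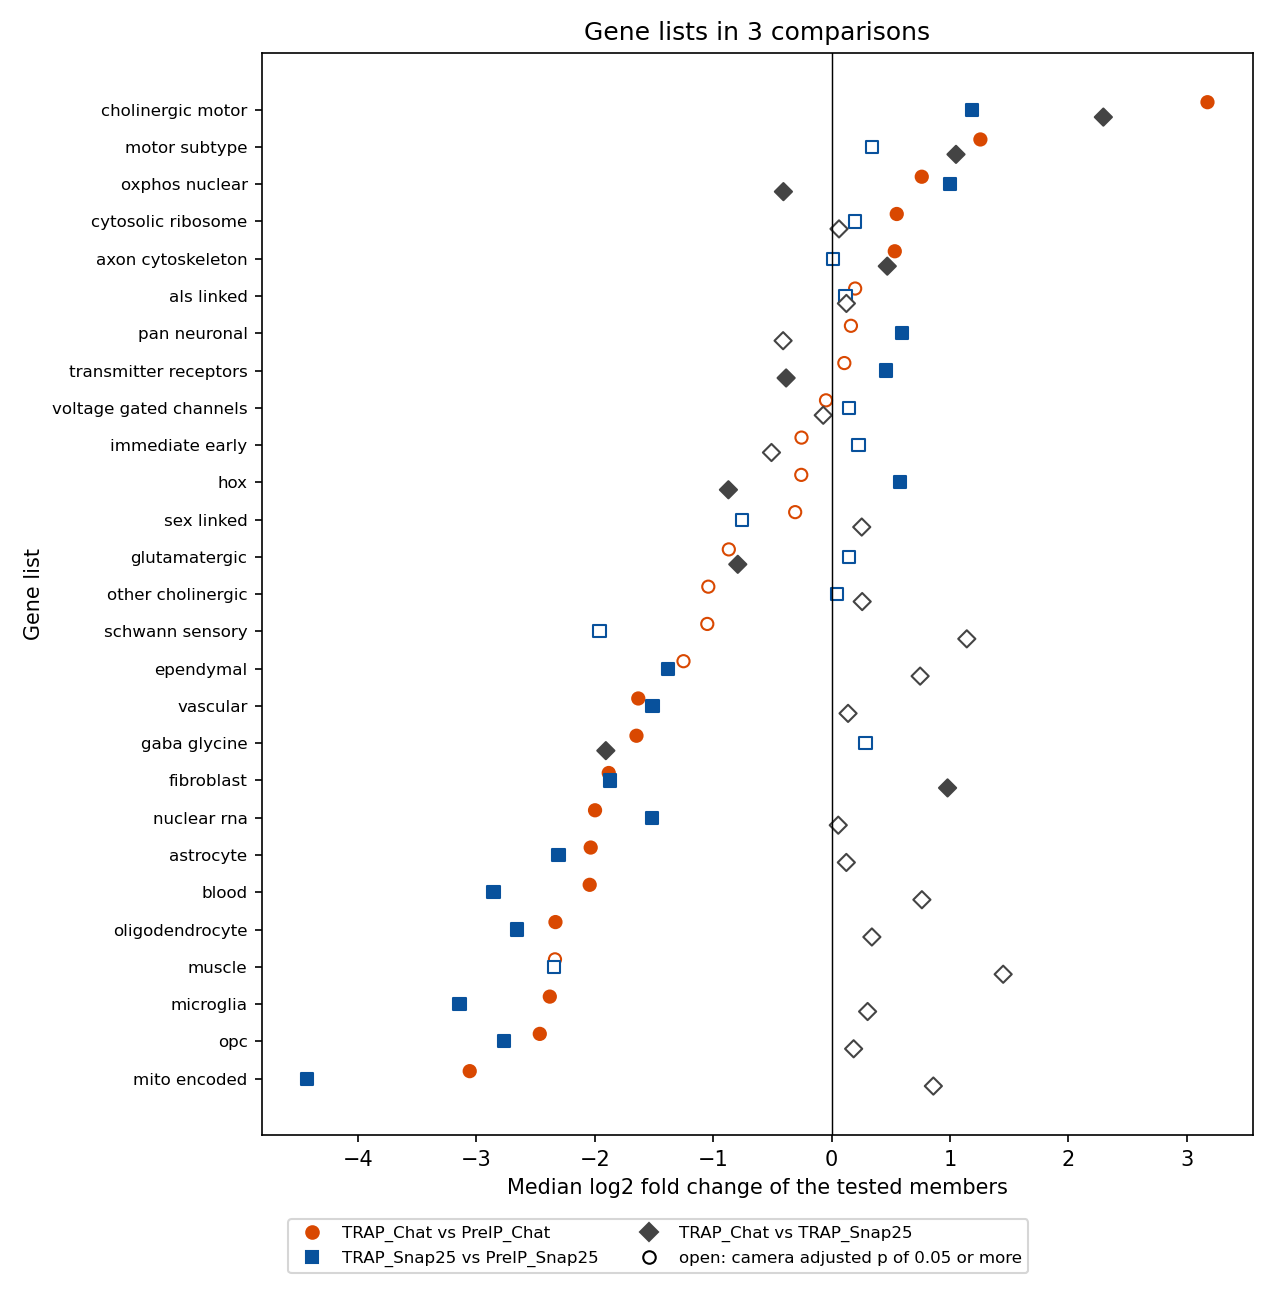
Median log2 fold change (horizontal axis) of the tested members of each of the 27 gene lists (vertical axis) in 3 comparisons. Filled symbols mark a camera adjusted p under 0.05 at the preset correlation, and open symbols a higher one. The cholinergic motor neuron list stood at 3.17, 1.19 and 2.29, and the list of inhibitory neurons at -1.65, 0.29 and -1.91.

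The series title sets motor neurons against all neurons, which the comparison of TRAP_Chat with TRAP_Snap25 addresses. Of 20 cholinergic motor neuron genes 18 were higher in TRAP_Chat, or 19 adjusted over the list alone, with a median 4.91-fold difference. Isl1, a transcription factor of motor neurons, was 9.05-fold higher (log2 fold change 3.18 ± 0.57, SE, n = 3 per group, edgeR adjusted p = 0.00268), and Chat was 6.38-fold higher (adjusted p = 1e-04). The list passed camera (adjusted p = 1.04e-22), and kept its call with an estimated correlation (adjusted p = 0.0197 with an estimated correlation). Slc18a3, the vesicular acetylcholine transporter, was 12.5-fold higher, at 1374.5 ± 404 against 110 ± 98.3 CPM (SD). Between the inputs of the lines its log2 fold change was 1.86 ± 0.51 (SE). This did not pass in the edgeR fit of the report, but did with no filter on low counts (edgeR adjusted p = 5.47e-07). Its change from input to pulldown differed between the lines by 1.78 ± 0.70, which did not pass in the fit of the report (adjusted p = 0.312). The input difference is thus part of the difference between the pulldowns. Slc18a3 lies within Chat, so that the assignment of its reads is uncertain while the strand setting is not given.

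Markers of inhibitory neurons were lower in TRAP_Chat. Of 17 genes of GABAergic and glycinergic neurons 12 were lower (13 adjusted over the list alone), with a median log2 fold change of -1.91, among them Npy 20.5-fold (log2 fold change -4.36 ± 0.58, SE, edgeR adjusted p = 0.000237), and Pvalb, a calcium-binding protein, 9.02-fold. This list kept its call with an estimated correlation (camera adjusted p = 8.26e-12, and adjusted p = 0.00822 with an estimated correlation). Of 17 glutamatergic markers 3 were lower and 1 higher (4 and 1 adjusted over the list alone), with a median of -0.79 (camera adjusted p = 0.000316, and adjusted p = 0.0514 with an estimated correlation). Nts was the higher member, at 3.16-fold. Of 25 Hox genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone), among them Hoxb8 4.99-fold lower, with a median of -0.87 (camera adjusted p = 6.63e-06, and adjusted p = 0.0514 with an estimated correlation). The largest differences of single genes included Hapln1, a link protein of the extracellular matrix, 12.9-fold lower, Fbxo40 14.2-fold lower and Nrn1, which encodes neuritin, 10.4-fold lower. Otp, a transcription factor, stood at 1.45 ± 1.71 against 39.0 ± 41.7 CPM (SD), with a log2 fold change of -4.69 ± 0.80 (SE), from -6.27 without TRAP_Chat replicate 3 to -3.32 without TRAP_Snap25 replicate 3.

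Structural and subtype genes differed as well. Of 17 genes of the axonal cytoskeleton 6 were higher and 1 lower (6 and 1 adjusted over the list alone), among them Prph 4.86-fold and the neurofilament gene Nefm 2.66-fold higher (camera adjusted p = 0.000316, and adjusted p = 0.226 with an estimated correlation). Of 11 markers of motor neuron subtypes 5 were higher and 1 lower (7 and 1 adjusted over the list alone), among them Wnt7a, a secreted signal, 5.86-fold higher (camera adjusted p = 0.0105, and adjusted p = 0.214 with an estimated correlation). Clic1, a chloride channel protein, Wnk4, a kinase that regulates ion transport, and S100a11, a calcium-binding protein, were 12.3-fold, 10.1-fold and 8.86-fold higher. Transmitter receptors had 6 of 33 members lower and 2 higher (7 and 2 adjusted over the list alone), among them Htr1a, a serotonin receptor, 9.20-fold lower and Htr2a, another serotonin receptor, 3.69-fold higher (camera adjusted p = 0.0116, and adjusted p = 0.706 with an estimated correlation). Without TRAP_Snap25 replicate 1 or 2 or TRAP_Chat replicate 1 the receptor list had a camera adjusted p of 0.0749, 0.0529 or 0.109. Voltage-gated channels went both ways, 4 of 30 higher and 4 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.737), with the calcium channel Cacna1d 3.77-fold higher and the potassium channels Kcna6 and Kcnc2 4.37-fold and 2.94-fold lower.

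For nuclear genes of the respiratory chain all 26 log2 fold changes of TRAP_Chat against TRAP_Snap25 were negative, with a median of -0.41, and 0 members passed by edgeR, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7, and over all genes DESeq2 and limma voom called 1 and 0. Camera gave adjusted p = 0.000815, and adjusted p = 0.706 with an estimated correlation. Fibroblast markers had 2 of 11 members higher (3 adjusted over the list alone, camera adjusted p = 0.0480, and adjusted p = 0.706 with an estimated correlation). That call ended without TRAP_Snap25 replicate 2 or 3 or TRAP_Chat replicate 1 or 2 (camera adjusted p = 0.413, 0.160, 0.144 and 0.106).

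In total 632 genes were higher and 441 lower in TRAP_Chat than in TRAP_Snap25 (edgeR), 570 and 393 of them over 2-fold, and 3445 had an unadjusted p under 0.05. The libraries of both groups did not overlap for 3145 genes, or 19.8%, where chance gives 10%. Counts of higher and lower genes were 1026 and 746 with DESeq2, 237 and 145 in a fit of these 6 libraries alone, and 1085 and 676 with no filter on low counts. Without TRAP_Snap25 replicate 2 or 3 there were 355 or 961 higher genes, and without TRAP_Chat replicate 2 there were 266 lower genes.

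A further comparison set the change from input to pulldown in the Chat line against that in the Snap25 line, which takes out differences that the inputs of the lines also show. Of 20 cholinergic motor neuron genes 10 rose more in the Chat line (18 adjusted over the list alone), with a median log2 difference of 2.22. Slc5a7, the choline transporter, had a difference of 2.56 ± 0.39 (SE, n = 3 per group, edgeR adjusted p = 0.00671) and Prph of 2.26 ± 0.35. Of 17 genes of inhibitory neurons 8 changed towards lower values in the Chat line (12 adjusted over the list alone), with a median of -1.92, among them Npy at -4.45 ± 0.74. Both lists passed camera (adjusted p = 2.42e-21 and 2.88e-13), and kept their calls with an estimated correlation (adjusted p = 0.0238 and 0.00547 with an estimated correlation). Clic1 and S100a11 fell in the Snap25 pulldown, by 2.13 and by 1.81 on the log2 scale, and rose in the Chat pulldown, by 1.84 and 1.71.

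This comparison called 96 genes higher and 70 lower (edgeR), all over 2-fold, with 1833 at an unadjusted p under 0.05. The differences did not overlap between lines for 2786 genes, or 17.5%, where chance gives 10%. All 96 and 70 were also called in the same direction in TRAP_Chat against TRAP_Snap25, which shares 6 libraries with it, where independent lists would share 3.81 and 1.94. In 20 simulated sets without change at most 1 gene was called by either comparison and 0 by both (edgeR). The correlation of the log2 fold changes was 0.711 in those sets and 0.926 in the data, and their covariance 0.328 and 1.24. The simulation leaves out real effects and gives all groups the same spread, whereas the real pulldowns varied more than the inputs. The independent lists leave out the shared libraries, so part of the excess may come from those libraries. Higher and lower counts were 292 and 209 with DESeq2 and 269 and 184 with no filter on low counts, and limma voom gave 106 lower genes. Leaving out a library gave 53 higher and 44 lower without PreIP_Snap25 replicate 1, 45 lower without its replicate 2, 54 and 38 without its replicate 3, 48 and 40 without PreIP_Chat replicate 1, 26 and 26 without its replicate 2, 46 and 46 without its replicate 3, and 152 higher without TRAP_Snap25 replicate 3.

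The inputs of the lines were compared as a background. By edgeR 0 genes were higher and 0 lower in PreIP_Chat than in PreIP_Snap25, with 133 at an unadjusted p under 0.05 and a smallest adjusted p of 0.819. Chance alone would give a share of 0.05 of the 15905 tested genes, and 133 is far fewer. The test was thus conservative for the inputs, and 0 calls do not show that they were alike. A fit of the input libraries alone gave 532 genes at an unadjusted p under 0.05 and also called 0. DESeq2 called 1 gene, Ercc6, a DNA repair gene next to Chat (log2 fold change 1.33, adjusted p = 0.00277), limma voom called 0, and a fit with no filter on low counts called 7. The libraries of both groups did not overlap for 1279 genes, or 8.04%, where chance gives 10%. Chat had a log2 fold change of 0.46 ± 0.29 and Snap25 of -0.59 ± 0.26 (SE, n = 3 per group), and neither passed by edgeR.

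**Figure D3:**
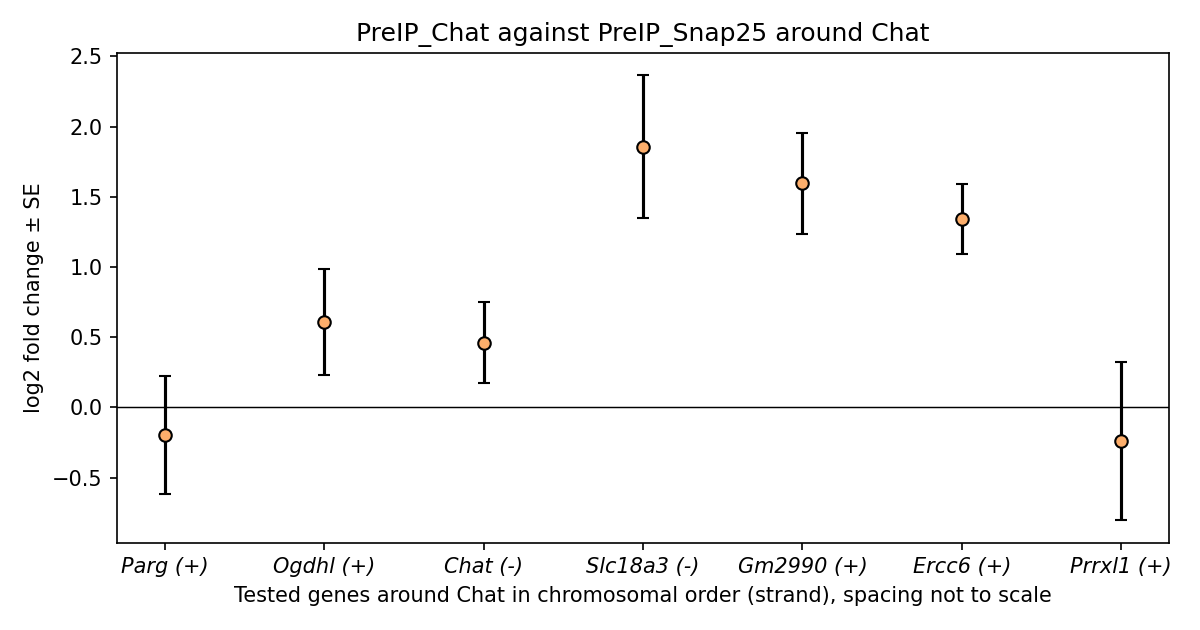
Log2 fold change of PreIP_Chat against PreIP_Snap25 (vertical axis) with its SE (bars) for the 7 tested genes in a window of 150 kb to either side of Chat, in chromosomal order with their strand (horizontal axis, not to scale). Slc18a3, Gm2990 and Ercc6 stood at 1.86, 1.60 and 1.34, and Chat at 0.46; none passed over all genes by edgeR with the filter on low counts, and with no filter Slc18a3 and Gm2990 did (adjusted p = 5.47e-07 and 0.0356).

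Few members of the lists passed between the inputs. By edgeR 0 of 20 cholinergic motor neuron genes and 0 of 11 fibroblast markers passed over all genes, 1 and 0 passed adjusted over the list alone, and 1 and 1 had an unadjusted p under 0.05. DESeq2 and limma voom also called 0 of either list over all genes. Both lists passed camera, with median log2 fold changes of 0.18 and 0.65 (adjusted p = 0.0335 and 4.6e-05), and both had adjusted p = 0.957 with an estimated correlation. Camera no longer called either list without PreIP_Chat replicate 2 (adjusted p = 0.174 and 0.0631), nor the cholinergic list without PreIP_Snap25 replicate 2 (adjusted p = 0.760). Genes of skeletal muscle had a median log2 fold change of 2.38 and did not pass (camera adjusted p = 0.0865). Their counts were concentrated in PreIP_Chat replicate 2, with 2052 for Acta1, an actin, 571 for Ckm, a creatine kinase, and 835 for Myh4, a myosin. With no filter on low counts edgeR called Acta1 and Mylpf, another member, higher in PreIP_Chat (adjusted p = 5.47e-07 and 0.000799). These were picked after their values were seen.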

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

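The tests on the Chat locus, on cholinergic cells in the input, on carry-over, on immunoglobulin-producing cells and on other splits of the samples were chosen only after the result was seen. The tests on the Snap25 locus and on antibody clones were written before theirs.

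The change from input to pulldown differed between the lines, by a test of the difference itself, for 96 genes that were higher and 70 that were lower in the Chat line (edgeR). Clic1 (3.97), S100a11 (3.52), Slc5a7 (2.56), Chodl (2.42) and Prph (2.26) had positive log2 differences, and Npy (-4.45), Fbxo40 (-4.20), Strip2 (-3.66), Cckbr (-3.43), Hapln1 (-3.35), Pvalb (-2.89), Slc17a6 (-2.23) and Hoxb8 (-2.22) negative ones, and the calls of these genes held in every alternative run, each library left out in turn included. Counts fell to 26 higher and 26 lower without PreIP_Chat replicate 2. They were 48 and 40 without PreIP_Chat replicate 1, 46 and 46 without its replicate 3, 53 and 44 without PreIP_Snap25 replicate 1, and 54 and 38 without its replicate 3. Without PreIP_Snap25 replicate 2 there were 45 lower genes, and without TRAP_Snap25 replicate 3 there were 152 higher genes.

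Another 12 named genes passed the same test but lost the call without some library, by edgeR. They were Wnk4 (log2 difference 3.40), Pdgfd (3.08), Uts2b (2.69), Nts (2.27), Chat (2.21), Nefm (1.87), S100b (1.48), Chrm3 (-3.07), Slc32a1 (-3.04), Htr1a (-2.71), Pax2 (-2.41) and Hoxb9 (-2.05). Without PreIP_Chat replicate 2 adjusted p was 0.0589 for Chat and Wnk4, 0.0546 for Uts2b, 0.0523 for Htr1a, 0.0527 for Slc32a1, 0.0696 for Nefm and Chrm3, 0.0793 for Pdgfd, 0.0893 for Pax2, 0.114 for Nts, 0.172 for S100b and 0.0650 for Hoxb9. Without PreIP_Chat replicate 1 it was 0.0920 for Pdgfd, 0.0837 for Pax2, 0.126 for Nts, 0.109 for S100b, 0.147 for Chrm3 and 0.0722 for Hoxb9, and without replicate 3 it was 0.0945 for Pax2, 0.0507 for Nefm and 0.0900 for Nts, S100b and Chrm3. Leaving out PreIP_Snap25 replicate 1 gave 0.0507 for Wnk4, 0.0580 for S100b, 0.126 for Chrm3 and 0.0559 for Hoxb9. Its replicate 2 gave 0.0899 for Pax2 and Chrm3, 0.0602 for Nts and 0.0628 for S100b, and its replicate 3 gave 0.0954 for Pdgfd, 0.0964 for Pax2, 0.115 for Nts, 0.0559 for Slc32a1, 0.120 for S100b, 0.116 for Chrm3 and 0.0706 for Hoxb9. Leaving out a TRAP_Chat library gave 0.0767 for Pax2, 0.0803 for Nts and 0.0858 for S100b (replicate 1), 0.0721 for Pdgfd, 0.0594 for Pax2, 0.0501 for S100b and 0.0779 for Chrm3 (replicate 2), and 0.0799 for Nts, 0.0772 for S100b and 0.0864 for Chrm3 (replicate 3). Leaving out a TRAP_Snap25 library gave 0.0555 for Pax2, 0.0561 for Nts, 0.0878 for S100b, 0.0601 for Chrm3 and 0.0527 for Hoxb9 (replicate 1), and 0.0514 for Pdgfd, 0.0753 for Nts, 0.0896 for S100b and 0.0921 for Chrm3 (replicate 2).

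Lists differed between the lines in the same way by camera. The cholinergic motor neuron list had a median log2 difference of 2.22 and the inhibitory list one of -1.92. Hox genes had -0.70 (3 of 25 lower, 7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000107, and adjusted p = 0.0945 with an estimated correlation). Glutamatergic markers had -0.78 (1 of 17 lower and 1 higher, 3 and 1 adjusted over the list alone, 0.000791, and adjusted p = 0.0864 with an estimated correlation). The axonal cytoskeleton had 0.31 (3 of 17 higher, 6 higher and 1 lower adjusted over the list alone, 0.0014, and adjusted p = 0.322 with an estimated correlation).

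A further 3 lists passed camera but lost the call without some library. Motor neuron subtypes had a median of 1.09 (1 of 11 higher, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0381, and adjusted p = 0.322 with an estimated correlation). The subtype list had adjusted p = 0.0887 without PreIP_Snap25 replicate 1, 0.0572 without PreIP_Chat replicate 3, 0.0667, 0.0616 and 0.0501 without TRAP_Snap25 replicates 1, 2 and 3, and 0.107 and 0.0983 without TRAP_Chat replicates 2 and 3. Transmitter receptors had a median of -0.31 (4 of 33 lower, 6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.661 with an estimated correlation). Without PreIP_Snap25 replicate 3, TRAP_Snap25 replicates 1 and 2 and TRAP_Chat replicate 1 the receptor list had adjusted p = 0.0842, 0.0857, 0.0616 and 0.126. Nuclear genes of respiration had a median of -0.21, with 0 of 26 passing by edgeR, DESeq2 or limma voom, 0 adjusted over the list alone and 2 lower at an unadjusted p under 0.05 by edgeR (camera adjusted p = 0.0329, and adjusted p = 0.887 with an estimated correlation). This list had adjusted p = 0.184 and 0.191 without PreIP_Snap25 replicates 1 and 2, 0.0748 without PreIP_Chat replicate 1, 0.0980 and 0.0616 without TRAP_Snap25 replicates 2 and 3, and 0.196 without TRAP_Chat replicate 3.

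Other splits of the samples were counted for each comparison. For the difference between the lines, 100 of 200 splits were drawn. The real one called 166 genes, the highest other 263, and 7 splits called as many as the real one, itself included, so chance was not excluded by this count. All 7 were among the 8 drawn splits that kept the real TRAP groups. These 8 are the real one and 7 that regrouped only the inputs. The other 92, which mixed the pulldowns of the lines, called at most 0 genes. Mixing puts the difference between the pulldowns into the spread within groups, so few calls were likely there. The splits therefore do not show what lies behind the calls. The other comparisons have 10 splits each, too few for a share under 0.05. The real split called 4273 genes and the highest other 0 in the Chat pulldown against its input. In the Snap25 pulldown against its input these were 3558 and 0, and in TRAP_Chat against TRAP_Snap25 1073 and 8. Thus 1 split reached the real count in each. Every other split mixed both groups, which puts their difference into the spread within groups. Its low count is therefore no support for the calls. For the inputs all 10 splits called 0, as did the real one (edgeR), against 133 genes at an unadjusted p under 0.05 and 1 by DESeq2.

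The 7 tested genes within 150 kb of Chat had a median log2 fold change of 0.61 in PreIP_Chat against PreIP_Snap25. This was as high as in 0.0842% of 1188 windows, which include the Chat window itself and overlap one another. Slc18a3 and Gm2990 overlap Chat, so the assignment of their reads is uncertain. Of the 7 genes 0 passed by limma voom or the edgeR fit of the report. DESeq2 called 1, Ercc6, and edgeR with no filter on low counts called Slc18a3 and Gm2990 (adjusted p = 5.47e-07 and 0.0356). The 3 with an unadjusted p under 0.05 by edgeR, which prompted the test, are part of that median. More RNA of cholinergic cells in that input is argued against by the 18 other measured cholinergic motor neuron genes, whose median was 0.13 (SD 0.279), where the locus genes with an unadjusted p under 0.05 began at 1.34. Extra copies of the region on the transgene may explain the pattern, but the 4 genes of the window that did not prompt the test had a median of only 0.13, and the extent of the transgene is not given. Ercc6 was also higher in TRAP_Chat than in TRAP_Snap25, by 1.97, but had only 0.18 ± 0.24 (SE) in TRAP_Chat against PreIP_Chat (adjusted p = 0.610), where the cholinergic motor neuron list had a median of 3.17, which goes against extra RNA from mainly the tagged cells for this 1 gene and leaves the rest of the region open. At the Snap25 locus the 2 neighbours tested had a median of -0.23, as low as in 15.4% of 1792 windows, which is too few genes to decide.

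TRAP_Chat replicate 1 held RNA of the mitochondrial ribosome at 26.7% of the mean of its input, against 1.21% and 1.43% in replicates 2 and 3. Carry-over of mitochondria alone was tested with its oligodendrocyte list, which stood 1.61 times above the higher of the other TRAP_Chat libraries. Its astrocyte list stood at 42.2% of input. These lists cannot decide the question, since replicates 2 and 3 also differed from each other. They had 11.5% and 23.4% for oligodendrocytes and 14.1% and 29.4% for astrocytes. Carry-over of total input RNA may have contributed, since the oligodendrocyte list stood at 37.7% of input and only 0.168% of 2980 abundant genes lay below 13.4% of input, against 2.79% and 0.772% in replicates 2 and 3. Blood genes, at 47.2% against 16.5% and 23.0% in replicates 2 and 3, and nuclear RNA, at 31.4% against 25.0% and 28.0%, were also highest in replicate 1, while the microglial list, at 18.9% against 15.6% and 20.4%, was not, and with 1 such library the question stays open. Intestinal genes, seen afterwards, stood above the input in this library and in replicate 3. Apob had 644 and 258 counts there, against 56, 26 and 20 in PreIP_Chat. Carry-over of input does not account for those genes. No biological explanation was tested.

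Immunoglobulin RNA was present in the TRAP libraries, with constant-region levels from 288 to 1183 CPM against at most 165 CPM in a PreIP library (over total counts, without TMM). For Ighg1, a source in untagged cells of the tissue is argued against by 0 counts in the 6 PreIP libraries together, against 29, 42 and 0 in TRAP_Snap25 and 132, 39 and 1 in TRAP_Chat (243 in all, and 111 without TRAP_Chat replicate 1), and Ighg2b had 0 and 23. Ighm made up 98.9% of the constant-region counts of the inputs and most of those of every TRAP library. It had 16594 of 17017 in TRAP_Chat replicate 1 and 2913 of 2928 in TRAP_Snap25 replicate 3. The constant-region levels above are thus mostly those of Ighm, for which a source in untagged cells stays open. RNA of few antibody-producing clones added at the pulldown could be a source, but the 2 leading genes held 42.1% of only 38 heavy-chain variable counts (exact Clopper-Pearson 95% interval 26.3% to 59.2%), and since this covers counting error only, with reads amplified and pooled over libraries, it stays open. Of 181 kappa variable counts, seen afterwards, 2 genes with 0 counts in the PreIP libraries held 81.2%, and 62.7% without TRAP_Chat replicate 1, which gave 130 of them; no biological explanation was tested.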

How the results depend on the processing

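The fit of protein-coding genes only was chosen after the data had been seen. The cause of the changes below was not tested. Leaving out a library or fitting fewer groups reduces the samples behind each estimate of the spread. That alone does not account for all changes. A fit of only the groups compared called 4855 genes against 4273 in the Chat pulldown, but 382 against 1073 in TRAP_Chat against TRAP_Snap25. The fit of all 12 libraries shares its estimate of the spread over pulldowns and inputs, although the pulldowns varied more (coefficients of variation 0.479 and 0.495 against 0.231 and 0.285). Its common value was 0.377. P-values of that fit may therefore be too small between the pulldowns and too large between the inputs.

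Of 218 calls of named genes 147 held in all alternatives and 0 reversed. Of 49 list calls 37 held in all alternatives set beforehand but the estimated correlation. The only values to reverse were those of Rpl10a in the Snap25 pulldown, which did not pass: its log2 fold change of -0.15 ranged from -0.46 without TRAP_Snap25 replicate 3 to 0.15 without PreIP_Snap25 replicate 3, and was 0.03 without TRAP_Snap25 replicate 2. RLE scaling, the filter of at least 1 CPM in 3 libraries and protein-coding genes only moved no count of calls by over 1.5 times.

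With DESeq2 TRAP_Chat against TRAP_Snap25 had 1026 higher and 746 lower genes, the difference between the lines 292 and 209, and the inputs 1 higher. With no filter on low counts these were 1085 and 676, 269 and 184, and 6 higher and 1 lower. Limma voom gave 106 lower genes for the difference between the lines. A fit of only the groups compared gave 890 higher genes in the Snap25 pulldown, and 237 higher and 145 lower in TRAP_Chat against TRAP_Snap25. The cause was not tested.

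Leaving out each library in turn gave 1191 to 1767 genes higher in the Chat pulldown, 675 to 1688 higher and 1298 to 2321 lower in the Snap25 pulldown, 355 to 961 higher and 266 to 574 lower in TRAP_Chat against TRAP_Snap25, and 26 to 152 higher and 26 to 97 lower for the difference between the lines. Genes higher in both pulldowns ranged from 493 to 1095, and genes lower in both from 877 to 1436. The lowest counts came without PreIP_Chat replicate 2 (1191, and 26 and 26), PreIP_Snap25 replicate 2 (675, 1298 and 493), TRAP_Snap25 replicate 2 (355) and TRAP_Chat replicate 2 (266). The counts of 961 and 152, the highest of their ranges, came without TRAP_Snap25 replicate 3.

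With an estimated correlation 0 lists were called higher and 0 lower in either pulldown against its input, 1 and 1 in TRAP_Chat against TRAP_Snap25, 1 and 1 for the difference between the lines, and 0 higher between the inputs, where camera with the preset correlation called 5 and 10, 5 and 10, 4 and 5, 3 and 5, and 2 higher. Fry called 3 lists lower in TRAP_Chat against TRAP_Snap25, 3 lower for the difference between the lines, and 0 higher between the inputs. Leaving out libraries gave 4 to 8 lists higher in the Snap25 pulldown (8 without PreIP_Snap25 replicate 1), 2 to 5 higher (5 without TRAP_Chat replicate 2) and 3 to 6 lower (3 without TRAP_Snap25 replicate 2) for the difference between the lines, and 0 to 5 higher and 0 to 5 lower between the inputs. For the inputs the higher lists were 5, 1, 4, 0 and 4 without PreIP_Snap25 replicates 1 and 2 and PreIP_Chat replicates 1, 2 and 3, and the lower lists 2, 2, 2 and 5 without PreIP_Snap25 replicates 1, 2 and 3 and PreIP_Chat replicate 1.

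An input and a pulldown with the same number share a suffix in the labels, whose meaning is not stated, and between the lines samples share a number, while the digits of 1 suffix occur in both lines under different numbers. The correlations of deviations from the group means under the same number were 0.0601, 0.102 and 0.127 between input and pulldown in the Chat line, where each library correlated best with its own number, and -0.0365, 0.167 and 0.147 in the Snap25 line, where that did not hold. Between the lines they were 0.0846, -0.0911 and -0.0909 for the inputs, where samples of unlike numbers reached 0.337, and 0.0228, 0.0320 and 0.0648 for the pulldowns. With a replicate block of each input with its pulldown there were 1986 higher and 2445 lower genes in the Chat pulldown, 1544 and 2119 in the Snap25 pulldown, and 118 and 88 for the difference between the lines, where Nts (adjusted p = 0.0574) and the list of motor neuron subtypes (0.0651) no longer passed. With a replicate block of the bare number TRAP_Chat against TRAP_Snap25 had 253 higher and 162 lower genes, with 34 of 52 named calls kept, and the inputs had 1 higher gene, Slc18a3 (adjusted p = 0.0208), and 1 lower list, while the cholinergic list no longer passed (0.0651). Of the named calls 76 of 79 held in the Chat pulldown and 57 of 61 in the Snap25 pulldown.

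Depth limits genes of low counts: 3 counts amount to 0.146 to 0.296 CPM. In simulated data, where changed genes had a mean of at least 1 CPM, a 2-fold change was recovered for at most 19.0% of them. Whether depth or the spread between libraries set that share was not tested.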

Other observations

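Motor neuron diseases are linked to many genes that motor neurons express. Of 29 measured ALS-linked genes 5 rose and 2 fell in the Chat pulldown (5 and 2 adjusted over the list alone), with Prph higher by 3.41 and 3110043O21Rik, the mouse C9orf72 gene, by 1.64, and Spg11, a gene of axonal upkeep, lower by -1.25 and Epha4, a guidance receptor, by -1.42 on the log2 scale (edgeR, against the input), and the list did not pass camera (adjusted p = 0.0714). In the Snap25 pulldown 5 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.103), among them Chchd10, a mitochondrial protein, by 1.67, and Sqstm1, an autophagy receptor, by 1.19. Of the serotonin receptor genes named by the rule, Htr2a was higher in the Chat pulldown, by 2.88 ± 0.38, and Htr1a lower, by -2.62 ± 0.36 (SE), while the list of transmitter receptors did not pass.

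Further lists did not pass camera in either pulldown unless stated in the report. In the Chat pulldown 3 of 7 ependymal genes fell (3 adjusted over the list alone, adjusted p = 0.0699), 5 of 25 Hox genes fell and 2 rose (5 and 2 adjusted over the list alone, 0.391), 4 of 15 immediate early genes fell and 1 rose (4 and 2, 0.564), 4 of 9 muscle genes fell by edgeR (4, 0.120), 3 by DESeq2 and 1 by limma voom, 3 of 7 genes of other cholinergic neurons fell and 1 rose (3 and 2, 0.391), and 4 of 9 Schwann cell and sensory neuron genes fell (4, 0.329). Transmitter receptors had 8 of 33 higher and 7 lower (8 and 8, 0.909) and voltage-gated channels 6 of 30 higher and 6 lower (8 and 7, 0.564). The receptor list had a median log2 fold change of 0.11, a mean of -0.06 and a camera direction up, and the channel list -0.05, 0.08 and up. In the Snap25 pulldown the immediate early list had 0.23, -0.09 and up, and the list of other cholinergic neurons 0.05, -0.31 and down. In TRAP_Chat against TRAP_Snap25 the muscle list had a median of 1.45, a mean of 1.28 and a camera direction down, the nuclear RNA list 0.06, -0.29 and down, the list of other cholinergic neurons 0.26, -0.26 and down, and the sex-linked list 0.25, 0.07 and down.

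Of the 5 tested sex-linked genes 0 passed by edgeR in any comparison. Xist, which is transcribed from the inactive X chromosome, lay between 1.28 and 54.1 CPM, and Ddx3y, on the Y chromosome, between 1.36 and 23.5 CPM, and each had counts in all 12 libraries.

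Some genes were high in only some libraries. The intestinal genes Fabp1, Fabp2, Apoa1, Apoa4 and Apob, chosen after their values were seen, had 356, 502, 511, 475 and 644 counts in TRAP_Chat replicate 1. Replicate 2 had 23, 66, 64, 26 and 24, and replicate 3 had 207, 129, 147, 113 and 258. In replicate 3 these were 12.5, 7.82, 8.91, 6.85 and 15.6 CPM over total counts. The highest values in any PreIP or TRAP_Snap25 library were lower, at 2.86, 4.03, 6.97, 2.07 and 8.41 CPM. The intestinal genes were thus raised in replicates 1 and 3 of TRAP_Chat, not in 1 library alone. Their effect on comparisons between the lines was not tested. Muscle genes were high in TRAP_Chat replicate 2 as in PreIP_Chat replicate 2, with 291 counts for Acta1, 117 for Ckm and 75 for Myh4. Acta1 had 28, 2052 and 137 counts in PreIP_Chat replicates 1, 2 and 3, and of the muscle genes that fell in the Chat pulldown Myh1 had adjusted p = 0.375, 0.0811 and 0.104 without PreIP_Chat replicate 2 and TRAP_Chat replicates 1 and 3. Tnnt3 had adjusted p = 0.491 and 0.0585 without PreIP_Chat replicates 2 and 3, and 0.110 and 0.139 without TRAP_Chat replicates 1 and 3. Scap, chosen in the same way, had 11378 counts in TRAP_Snap25 replicate 2. Cyp2j5 had 19, 22 and 32 counts in the PreIP_Chat libraries and 0 in the 6 libraries of the Snap25 line. Yam1, by contrast, had the most counts in every TRAP library of both lines and was high in all groups. It took 10.9% ± 6.26 of the counts in TRAP_Chat, 10.4% ± 6.04 in TRAP_Snap25, 9.10% ± 5.25 in PreIP_Chat and 5.41% ± 4.60 in PreIP_Snap25 (SD, n = 3). It was taken as a feature at or beside ribosomal RNA sequence in the annotation.

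Rpl10a, the gene fused to the tag, had a log2 fold change of -1.22 ± 0.44 in the Chat pulldown (SE, edgeR adjusted p = 0.0475). This rests on few counts, from 44 in TRAP_Chat replicate 1 to 175 in PreIP_Chat replicate 3. Whether reads of the gene were assigned elsewhere was not tested. Adjusted p was 0.125, 0.0733 and 0.118 without PreIP_Chat replicates 1, 2 and 3, 0.118 and 0.127 without TRAP_Chat replicates 1 and 3, 0.0662 with no filter on low counts and 0.0549 with protein-coding genes only. Over all alternatives adjusted p ranged from 0.0194 to 0.127. Reads of the tagged transcript and of the endogenous gene cannot be separated in these counts.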
